A study of Homo sapiens with 3 samples.

How the data were processed

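RNA from L428tetPU.1 cells was measured on 3 Illumina bead arrays, 1 each at day 0, day 1 and day 3 after tetracycline was taken away. They derive from L428, an established cell line of classical Hodgkin lymphoma, and carried a PU.1 (SPI1) gene that is kept off while tetracycline is in the medium, at 500 ng/ml per the labels. The description of the design names 4 independent experiments for each RNA sample, but each day has 1 column of values, and whether RNA was pooled is not given in the sources used here. The RNA was extracted with TRIzol, amplified with a TotalPrep kit and labelled with biotin, per the labels' protocols. The arrays were read with BeadStudio 3.3.7, per the submitters' processing notes.

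The deposited file of non-normalized values holds 1 bead intensity and 1 detection p-value for each of 48701 probes and each array, per the file headers. The intensities were on a linear scale, and the lowest on each array lay between 17.1 and 18.1. The detection p-value that the authors deposited falls as the intensity rises. The authors' deposited value table holds log2 values whose normalization is not given in the sources used here. Set against the intensities, each value equalled the log2 intensity less the 75th percentile of its array, less the median of the probe over the 3 arrays, to within 1e-05. The scale, the centring and the direction of that table are known from this comparison, and the median of each of its columns was 0. The median of 100.0% of its probes over the 3 arrays was also 0, so it holds differences between days and no levels.

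The intensities were corrected for background with the normexp model of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values. An offset of 16 was added, the 3 arrays were quantile normalized together, and log2 was taken. The inferred background mean was 33.2 at day 0, 32.5 at day 1 and 33.0 at day 3, with an SD of 9.84, 9.48 and 9.86. The offset draws the changes of dim probes toward 0, and quantile normalization gives the arrays one distribution of signals, so a shift of most genes in one direction would be removed. Everything else was computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and the figures were drawn with matplotlib 3.10.9.

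Gene names came from a table of the platform's annotation, updated through a RefSeq gene table of GRCh38.p14. Of the 48701 probes, 24303 had 1 gene symbol, 0 had several and 24398 had none there and stayed unnamed. The gene ID named 24089 probes and the accession named 50, and 164 kept the symbol of the platform. The named probes stood for 19367 genes, 3093 of them with more than 1 probe. The brightest probe of a gene, by its mean normalized log2 signal over the 3 arrays, stood for the gene. No genome build is named in the files, so no coordinates are given. Probes of near-identical genes, such as those of the HLA, IFITM, OAS and GBP families, can also read their relatives.

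A probe with a detection p-value under 0.01 was taken as above background. A gene was measured in a comparison if its probe was above background on at least 1 of the 2 arrays. With 1 array per day no test was possible and no p-value between days was computed. Instead, a fixed size rule was used. A gene was called higher or lower if it changed by at least 2-fold. If only 1 of the 2 arrays had it above background, the bound had to reach 2-fold too. The bound sets the brighter array's value against the lowest value above background on the dimmer array, or against the dim probe's own value where that was higher, and is written "at least N-fold". In what follows, "rose" and "fell" are used of genes that passed this rule. The error of a change was taken from genes with 2 probes above background on all arrays, as the SD of the difference between their changes divided by the square root of 2. That is error between probes. It leaves out differences between cultures and between RNA preparations.

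The comparisons were day 1 against day 0, day 3 against day 0, and day 3 against day 1. The rule for named genes was fixed before the data were examined, as were the size rule, 29 gene lists and 10 alternatives of the processing. The rule took SPI1 first. For day 1 and day 3 against day 0 it took the 10 largest rises and 10 largest falls among genes above background on both arrays, and the 5 largest of each by bound. From each list it took up to 4 members past the size rule with the largest change at day 3, or 2 if none passed. It always took 24 further genes, among them CDKN1A, MYC, PRDM1, BCL6, IRF4, PAX5, GAPDH and ACTB. Where 5 or fewer members of a list passed the rule they were all named, and those outside the rule for named genes were chosen after their values were seen. For each list, the median change of its measured members was set among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays and is no p-value. The lists cover myeloid, B cell and plasma cell genes, MHC class I and II genes, and PU.1 partners and lineage transcription factors. They also cover cell cycle and apoptosis genes, NF-kB, AP-1, JAK-STAT and interferon genes, and genes of Reed-Sternberg cells. Others hold ribosome, stress, metabolic and lysosome genes, markers of T and NK, erythroid and stromal cells, and control genes. Some genes are in more than 1 list. Of the genes and lists set in advance, 3 genes and 1 list are not reported here.

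The normalization and the size rule were tested on simulated data for the real genes. The 200 changed genes were drawn from those above background on all 3 arrays, so rises from below background were not simulated. In the simulation of day 1 against day 0, 37 of 50 genes changed by 2.5-fold passed the rule, as did 46 of 50 at 4.00-fold, 46 of 50 at 8.00-fold and 48 of 50 at 16.0-fold. Of 8811 unchanged genes 7 passed. In the simulation of day 3 against day 0, 22 of 50 genes changed by 2.00-fold and 48 of 50 changed by 4.00-fold passed, with 4 of 8814 unchanged genes. The simulated noise was 0.15 log2 per array, while the probe error of a change in the data was 0.37 at day 1 and 0.29 at day 3. Simulated arrays with probe error alone gave a mean of 60.0 genes past 2-fold at day 1, so the 7 here understates such calls. These figures cover the procedure and not the spread between cultures.

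The alternatives were no background correction, scaling to the median of detected probes, the authors' processed values, an offset of 50, a detection p-value under 0.05, detection on all 3 arrays, no detection filter, the mean of a gene's probes, and size rules of 1.5-fold and 3-fold. The precision of each value is limited by the 1 array per day.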

Results

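Gene expression was measured in L428tetPU.1 cells on 3 bead arrays, at day 0, day 1 and day 3 after withdrawal of the tetracycline that held an inducible PU.1 gene off. PU.1, encoded by SPI1, is a transcription factor of myeloid and B cells. The series followed what its induction does to the transcripts of a Hodgkin lymphoma cell line. Each day had 1 array and no replicate, so no value below has a replicate error. Of 48701 probes, 10838 were above background at day 0, 11317 at day 1 and 11272 at day 3, or 22.3%, 23.2% and 23.1%. The median intensity was 36.8, 35.9 and 36.7. Over probes above background on all arrays, the correlation of log2 signals across probes was 0.917 between day 0 and day 1, 0.954 between day 0 and day 3, and 0.958 between day 1 and day 3. No 2 arrays shared more than 0.938% identical intensities.

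The 1 named probe for SPI1 (ILMN_1696463) was not above background on any array. Its intensity was 40.8 at day 0, 35.3 at day 1 and 38.9 at day 3, with detection p-values of 0.152, 0.263 and 0.187. The lowest intensity above background was 70.4, 64.5 and 67.0 on the same arrays. These data therefore hold no measured rise of PU.1 RNA, and no fold is given for it. Whether this probe reads the transcript of the introduced gene is not given in the sources used here.

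**Figure D1:**
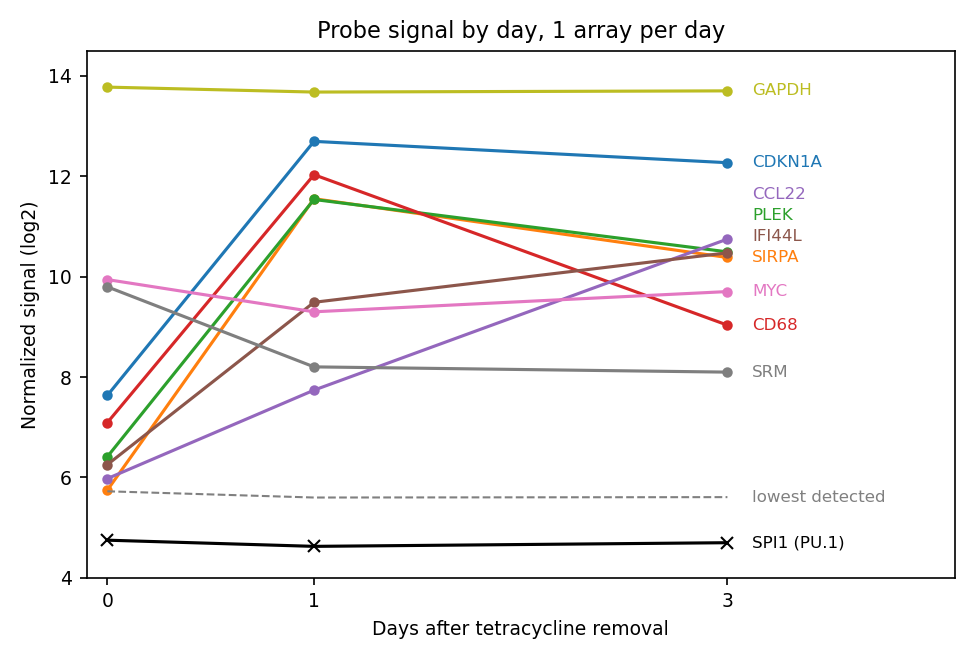
Normalized log2 signal (vertical axis) of selected genes at day 0, day 1 and day 3 after tetracycline removal (horizontal axis, days), with 1 array and hence 1 point per day. The dashed line marks the lowest signal above background; the SPI1 probe stays below it at every day, CDKN1A rises by 5.06 log2 by day 1, CD68 falls back after day 1 and CCL22 goes on rising to day 3.

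The first day after tetracycline removal was compared with day 0 to find the early changes. SIRPA, an inhibitory receptor of myeloid cells, rose by 5.81 log2, the widest rise among genes above background on both arrays. PLEK, a protein kinase C substrate of platelets and leukocytes, rose by 5.13, and CD68, a lysosomal glycoprotein of macrophages, by 4.94. CDKN1A, which encodes an inhibitor of cyclin-dependent kinases, rose 33.4-fold. PRG2, the major basic protein of eosinophils, rose by 4.93, the ERK phosphatase gene DUSP5 by 4.41 and the dendritic cell gene LAMP3 by 4.21. The rises of PTPN6 and INPP5D, both phosphatases that dampen signalling in blood cells, were 4.02 and 3.78, and that of DSE was 3.80. Some genes were above background at day 1 and not at day 0. Of these ARHGAP9 was at least 42.2-fold higher, RAPGEF3 at least 30.1-fold, HOPX at least 22.9-fold, LAD1 at least 22.7-fold and CLEC4A, a lectin receptor of dendritic cells, at least 22.6-fold. A second probe for LAD1 rose by 2.06 log2.

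The falls at day 1 were smaller. ADGRF5, an adhesion receptor, fell by 3.66 log2 and MTURN by 3.04. DYNC2LI1, a subunit of the dynein of cilia, fell by 2.75, and its second probe fell by 2.30. Next came DBN1, an actin-binding protein, at -2.53, DCDC2 at -2.40, CHAC2 at -2.39, the mitochondrial protein gene CISD1 at -2.38, PIWIL1 at -2.31, RIMBP2 at -2.24 and FAM117B at -2.18. By bound, ADGRV1 was at least 5.82-fold lower, RDH10 at least 5.21-fold, DTWD1 at least 4.54-fold and PLS1 at least 3.88-fold. TRIM9 was at least 4.61-fold lower, but its probes disagreed, with changes of 0.03 and -1.41 on the others.

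In all, 856 genes rose and 742 fell at day 1, of 9311 measured. Of the rises 244 reached 4-fold, against 28 of the falls, and 148 rises and 53 falls rest on a bound. The probe error of a change was 0.37 log2 (SD, 489 genes with 2 probes), below the 1 log2 of the size rule, and simulated arrays with probe error alone gave a mean of 60.0 genes past it. Every simulated gene had the error of these 489, which were above background on all arrays, and no bound was applied. The 60.0 therefore does not cover the error of dimmer genes. In the authors' values 642 genes rose and 854 fell, so that the share of rises among changed genes was 42.9% in place of 53.6%. Some calls of genes named for day 1 in the Results ended in an alternative, and those of genes named under other observations are given there. In the authors' values the calls of BCL6, EBF1, PSMB8, KIF2C, CENPE, BIRC5, FAS, BAK1, DAPK1, CASP6, CYCS and SPRY1 ended. Without background correction those of BCL6, EBF1, PSMB8, FCGR2A, SKP2, TCF12, CCNE1, BIRC5, SPC25, BAK1, CASP6, CYCS and SPRY1 ended.

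Interferon response genes had a median change of 1.69 log2 at day 1 over 43 measured members. Of these 30 rose and 0 fell. OAS3, which senses double-stranded RNA, was at least 14.8-fold higher, IRF7, a regulator of interferon genes, at least 8.36-fold, and IFI44L rose by 3.23 log2. B cell genes had a median of 1.75. Of 16 measured members 11 rose and 0 fell, while 31 more had probes that were not above background on either array, among them PAX5, MS4A1, CD79A and CD79B. BTK, a kinase of B cell receptor signalling, was at least 6.42-fold higher, the tetraspanin gene CD53 at least 5.50-fold, and the receptor CD40 rose by 2.71 log2. Myeloid genes had a median of 1.46. Of 11 measured members 6 rose and 0 fell, and 36 more, CSF1R included, were not above background. The integrin gene ITGAM was at least 4.60-fold higher and the Fc receptor gene FCGR2A at least 2.55-fold. Each of these 3 medians lay above all 10000 random lists. Those of B cell and myeloid genes depend on the detection filter. At a detection p-value under 0.05 the median was 0.63 for B cell genes and 0.74 for myeloid genes. With no filter they were 0.11 and 0.045. Over genes above background on all arrays the median was 1.55 for 9 B cell genes and 0.59 for 6 myeloid genes. The interferon median was 1.57 at a detection p-value under 0.05 and 1.35 with no filter.

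Antigen presentation and signalling genes also lay high at day 1. MHC class II genes had a median change of 0.86 log2, with all 15 measured and 3 past the rule. These were HLA-DPB1 at 1.70, HLA-DOA at 1.29 and CIITA, their transcriptional activator, at 1.48. The invariant chain gene CD74 changed by 0.39. Of 12 measured MHC class I and antigen processing genes 5 rose, with a median of 0.84, namely HLA-F at 1.75, the peptide transporter genes TAP1 at 1.54 and TAP2 at 1.18, TAPBP at 1.35 and PSMB8 at 1.04. NF-kB target genes had a median of 0.77. Of 46 measured 17 rose and 0 fell, with TNFAIP2 at least 4.28-fold higher and TNFAIP3, which restrains NF-kB, up by 1.37, while NFKBIA changed by 0.13. Of 28 JAK-STAT and cytokine feedback genes 10 rose and 1, STAT5B, fell by 1.57, with a median of 0.61. Reed-Sternberg cell genes, the list for the tumour cells of Hodgkin lymphoma, had 9 rises and 0 falls among 40 and a median of 0.47. Most of these rises were also among those of the NF-kB list. The activation marker TNFRSF8 (CD30) changed by 0.19. Of 21 AP-1 and immediate early genes 4 rose, DUSP5, MAFF (at least 3.51-fold), SPRED2 (2.14) and EGR1 (1.45), and SPRY1 fell by 1.13, with a median of 0.47 that was 0.12 with no detection filter. The medians of the MHC, NF-kB, JAK-STAT and Reed-Sternberg lists lay above all 10000 random lists, and that of the AP-1 list above 9954.

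Transcription factor genes went both ways at day 1. Of 35 PU.1 partners and lineage factors 7 rose and 2 fell, KLF2 by 1.69 and TCF12 by 1.06, with a median of 0.26 above 9887 random lists that was 0.042 with no detection filter. EGR1 rose by 1.45 and BCL6, a germinal centre repressor, by 1.02, a call that ended in the authors' values, at 0.85, and without background correction, at 0.92. LMO2, ETS1, ETV6 and EBF1, named after their values were seen, also rose, and LMO2 had the widest change of the list. From day 1 to day 3 LMO2, ETS1 and ETV6 fell. The plasma cell regulator PRDM1 rose by 1.91, but its second probe changed by 0.50, so its probes disagreed. IRF4 changed by 0.00. Of 11 plasma cell genes 1, PRDM1, rose and 1, CRELD2, fell by 1.02, with a median of 0.00.

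Growth genes gave a mixed picture at day 1. Of 23 cell cycle inhibitors and antiproliferative genes 5 rose and 0 fell. Beside CDKN1A these were the MYC antagonist gene MXD1 at 2.84 log2, TXNIP at 2.57, BTG1 at 1.62 and the damage-response gene GADD45A at 1.49. The list's median was 0.10 and -0.00 in the authors' values, and CDKN1B changed by -0.38. Among 23 G1 cyclin, MYC and E2F genes CCND2 rose by 1.16 and CCND3 by 1.36. CCND1 fell by 1.43, CCNE1 by 1.11, TFDP1 by 1.08 and SKP2, an F-box protein that targets CDKN1B, by 1.01. The median there was -0.04, and MYC changed by -0.64. Of 48 DNA replication genes 4 fell, MCM10 by 1.54, GINS2 by 1.33, TIPIN by 1.09 and GMNN by 1.07, and MCM5 rose by 1.35. Their median of -0.41 lay above 27 of 10000 random lists. Of 61 mitosis genes 5 fell and 3 rose, 8 and 1 in the authors' values and 3 and 3 without background correction. CCNA2 fell by 1.52, MAD2L1 by 1.16, BIRC5 by 1.15 and SPC25 by 1.08, CENPM fell as well, and KIF20B rose by 1.53, CENPE by 1.15 and KIF2C by 1.08. Their median was -0.06. Ribosome biogenesis and MYC target genes had the lowest median of the 29 lists, -0.65, below that of every random list. Of 39 measured 7 fell and 0 rose, among them SRM, which makes spermidine, by 1.59, RRP9 by 1.36 and NOP16 by 1.35. The median of genes above background on both arrays was -0.09. Less that, the medians were -0.56 for ribosome biogenesis, -0.33 for DNA replication and 0.02 for mitosis. In the authors' values they were -0.59, -0.36 and -0.06, so that mitosis genes have no settled direction at day 1.

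Of 27 pro-apoptotic genes 4 rose at day 1, BMF (at least 4.68-fold), FAS (1.17), DAPK1 (1.15) and BAK1 (1.05). ENDOG was at least 2.96-fold lower, and CASP6 fell by 1.12, CYCS by 1.12 and PMAIP1 by 1.04. In the authors' values 1 of these genes rose and 2 fell, and without background correction 3 rose and 2 fell. The median was 0.22, in the authors' values 0.13 and with no detection filter 0.11, and BCL2L11 was not above background. Of 16 anti-apoptotic genes PIM2 rose by 1.82, CFLAR, a caspase inhibitor, by 1.57 and TNFAIP3 by 1.37, and BIRC5 fell by 1.15. Their median of 0.65 lay above 9995 random lists. MCL1 changed by 0.11.

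**Figure D2:**
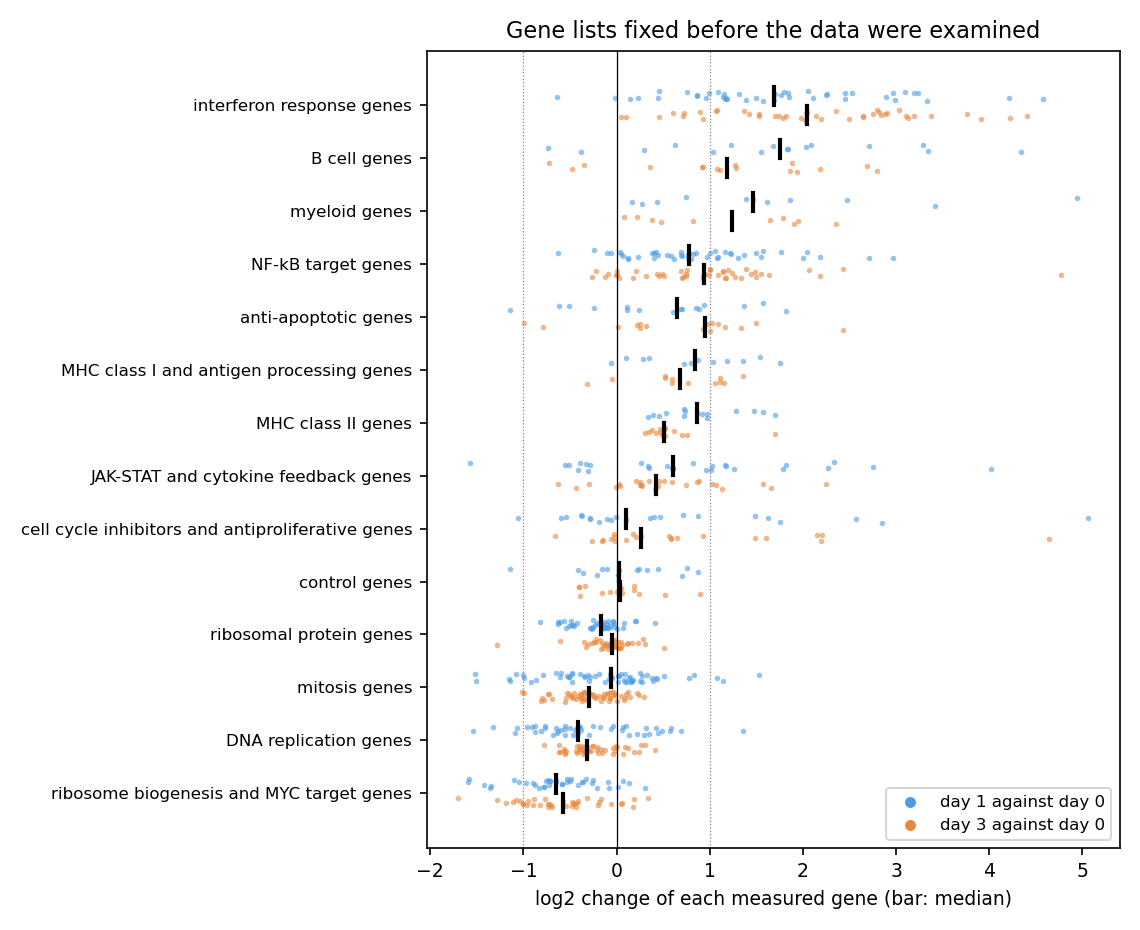
log2 change (horizontal axis) of each measured member of 14 gene lists (vertical axis), at day 1 (blue) and day 3 (orange) against day 0, with 1 array per day. Black bars are list medians and dotted lines mark 2-fold; the median of interferon response genes is 1.69 and 2.05, and that of ribosome biogenesis and MYC target genes -0.65 and -0.57. Control genes have medians of 0.03 and 0.04, the first of which is 0.21 under median scaling and the second -0.08 in the authors' values.

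Day 3 was compared with day 0 for the later state. CCL22, a chemokine of Reed-Sternberg cells and dendritic cells, rose 27.3-fold, followed by CDKN1A at 24.9-fold. SIRPA rose by 4.64 log2, IFI44L by 4.22, PLEK by 4.08, the junction protein gene CGNL1 by 3.98, the cytokine subunit gene IL12A by 3.95, LAMP3 by 3.92, DUSP5 by 3.62 and XKR4 by 3.35. Among genes above background only at day 3 of this pair, CLEC4A was at least 52.5-fold higher, LAD1 at least 26.9-fold, the adenosine deaminase gene ADA at least 15.5-fold, OAS3 at least 13.2-fold and IRF7 at least 12.4-fold. The falls were smaller. ADGRV1 fell by 2.03, the death receptor gene TNFRSF21 by 2.02 and the mitochondrial dicarboxylate carrier gene SLC25A10 by 1.96. ADISSP fell by 1.84, DBN1 by 1.83, GCAT by 1.71, SRM by 1.70, the mitochondrial ribosomal gene MRPS34 by 1.67, DUS3L by 1.63 and the RNA polymerase subunit gene POLR2L by 1.60. By bound, PACSIN3 was at least 3.28-fold lower, ENDOG at least 2.94-fold, DLEU1 at least 2.67-fold, ZNF69 at least 2.63-fold and PUSL1 at least 2.27-fold.

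At day 3, 455 genes rose and 196 fell, of 9190 measured. Of the rises 128 reached 4-fold, against 3 of the falls, and 96 rises and 9 falls rest on a bound. The probe error was 0.29 log2 (SD, 489 genes), and simulated arrays with probe error alone gave a mean of 4.71 genes past the rule. That count has the same limit for dimmer genes as at day 1. The authors' values gave 315 rises and 259 falls, a share of rises of 54.9% in place of 69.9%. They shift the median of genes above background on both arrays by -0.10. Without background correction 98 genes fell, and 97 with an offset of 50.

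Interferon response genes had the highest median of the 29 lists at day 3, 2.05 log2. Of 43 measured 33 rose and 0 fell, with IFI44L, LAMP3, OAS3 and IRF7 in front. B cell genes had a median of 1.19, with 8 rises and 0 falls among 16. CD53 was at least 3.76-fold higher and BTK at least 4.24-fold, CD40 rose by 2.19 and SWAP70 by 1.94. The median was 0.60 at a detection p-value under 0.05, 0.075 with no filter and 1.11 over 9 genes above background on all arrays. Myeloid genes had a median of 1.23, with 4 rises and 0 falls among 10, namely CD68 at 1.94, and ITGAM, ITGB2 and FCGR2A at least 3.10-fold, 2.94-fold and 2.61-fold higher. Their median was 0.45 at a detection p-value under 0.05, 0.049 with no filter and 0.43 over the 6 genes above background on all arrays. NF-kB target genes had a median of 0.94, with 20 rises (12 in the authors' values) and 0 falls among 46, led by CCL22, BCL2A1 at 2.43 and CD40. TNFAIP3 rose by 1.16 and NFKBIA changed by 0.21. Of 16 anti-apoptotic genes 6 rose and 0 fell, among them BCL2A1, BIRC2 at 1.33 and CFLAR at 2.82-fold, with a median of 0.95, and 3 rose in the authors' values and 4 without background correction. MCL1 changed by 1.00, just short of the rule, and its second probe by 0.20. The medians of these 5 lists lay above all 10000 random lists.

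MHC class I and antigen processing genes had a median of 0.68 at day 3. Of 12 measured 5 rose, TAP1 by 1.36, TAP2 by 1.16, HLA-F and HLA-E by 1.11 and PSMB8 by 1.05, of which only TAP1 passed in the authors' values. Of 15 MHC class II genes 0 passed the rule, with a median of 0.51. HLA-DOB was at least 1.91-fold higher and CD74 changed by 0.46 on its first probe and 1.20 on its second. Of 39 Reed-Sternberg cell genes 10 rose (6 in the authors' values) and 0 fell, with a median of 0.43, in the authors' values 0.25. Beside CCL22 these included TNFSF4 at 1.57, and TNFRSF9 and LGALS9 at least 3.75-fold and 2.10-fold higher, while TNFRSF8 changed by -0.55. Most of the Reed-Sternberg rises were also among those of the NF-kB list. Of 20 AP-1 and immediate early genes 5 rose and 0 fell, DUSP5, MAFF (at least 3.49-fold), EGR1 (2.07), SPRED2 (1.44) and ATF3 (1.12). Their median was 0.58, and 0.35 with no detection filter. Of 27 JAK-STAT and cytokine feedback genes 6 rose and 0 fell, among them SOCS2 (at least 3.93-fold), IL10RA (1.66), PTPN6 (1.57) and JAK2 (1.14). The median was 0.42, above 9997 random lists, and 0.26 in the authors' values. There 3 rose, and 4 rose without background correction. The other medians of this group lay above all 10000.

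Among transcription factors, EGR1 and PRDM1 rose at day 3 and BCL11A fell by 1.04, of 35 measured. The median was 0.01, and -0.04 in the authors' values. PRDM1 rose by 2.71, yet its second probe changed by 0.02. Of 11 plasma cell genes PRDM1 and XBP1 (1.13) rose and 0 fell, with a median of -0.03 that was 0.051 at a detection p-value under 0.05. BCL6 changed by 0.99, IRF4 by -0.15, CCND2 by 0.93, MYC by -0.24 and CDKN1B by -0.14.

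Of 23 cell cycle inhibitors 5 rose at day 3 and 0 fell, CDKN1A by 4.64, MXD1 by 2.21, TXNIP by 2.19, GADD45A by 2.15 and BTG1 by 1.61, with a median of 0.26 above 9941 random lists. Of 25 pro-apoptotic genes BNIP3L rose by 2.48, BNIP3 by 2.25 and BMF at least 3.19-fold, and ENDOG fell, with a median of 0.12 and, in the authors' values, -0.02. Of 23 G1 cyclin, MYC and E2F genes 1, SKP2, fell by 1.08 and 0 rose, with a median of -0.10. Of 39 ribosome biogenesis and MYC target genes 8 fell and 0 rose, with 11 falls in the authors' values and 4 without background correction. SRM fell by 1.70, RRP9 by 1.28, CCT5 by 1.19 and NOP16 by 1.11, and the median of -0.57 was below that of every random list. Of 48 DNA replication genes 0 passed the rule, with a median of -0.32. Of 60 mitosis genes 1, CDC20, fell by 1.02, with a median of -0.30. Each of these medians lay above 2 of 10000 random lists. The median of genes above background on both arrays was -0.08. Less that, the medians were -0.50 for ribosome biogenesis, -0.24 for DNA replication and -0.22 for mitosis. In the authors' values they were -0.58, -0.24 and -0.26. Among genes named for day 3 in the Results, the calls of HLA-E, HLA-F, TAP2, PSMB8, ATF3, JAK2, TNFAIP3, XBP1, BCL11A, LGALS9 and PUSL1 ended in the authors' values. Those of BCL11A, BIRC2, DLEU1, FCGR2A, LGALS9, PSMB8, PUSL1 and ZNF69 ended without background correction.

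**Figure D3:**
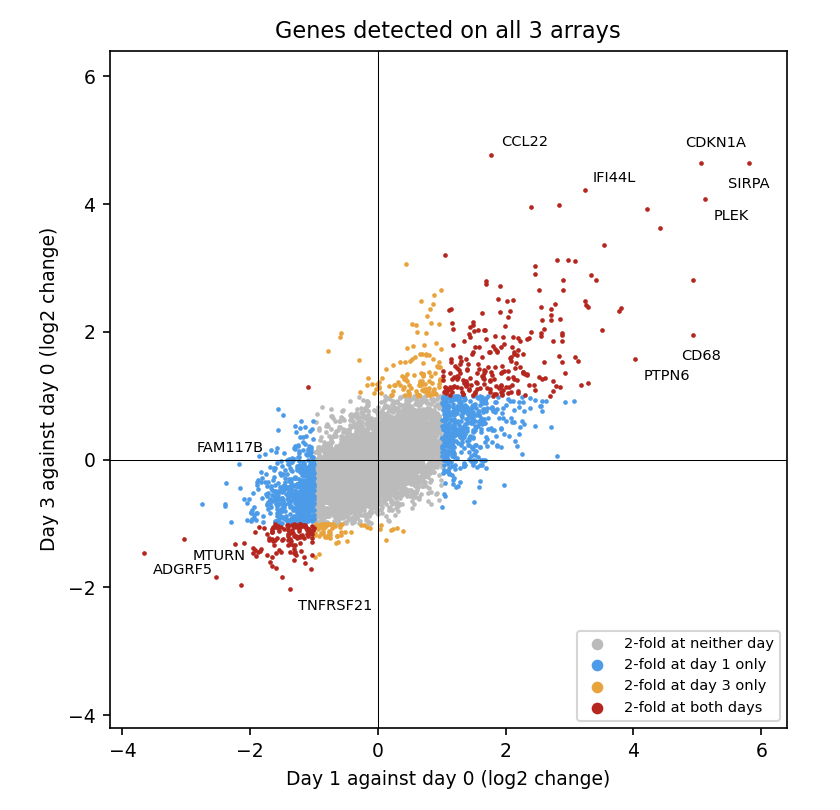
log2 change at day 3 (vertical axis) against log2 change at day 1 (horizontal axis), both against the same day 0 array, for 8090 genes above background on all 3 arrays. Each point is 1 gene, coloured by the day at which it passed the 2-fold rule. The correlation across genes is 0.71, against 0.58 in simulated arrays that share a day 0 array and hold probe error alone. Spread between cultures or RNA preparations is not part of that 0.58.

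The changes at both days were then set side by side, and day 3 was compared with day 1. Of 9001 genes measured in both comparisons with day 0, 304 rose at both days and 136 fell at both. These were 215 and 183 in the authors' values and 233 and 69 without background correction. Independent lists of these sizes would share 41.8 and 16.2, and simulated arrays without effect, with probe error alone, a mean of 1.02. Neither figure covers both the effects and the shared day 0 array, and part of the excess may come from that array, which cannot be split. The correlation of changes across genes was 0.71 (Spearman 0.66), against a simulated 0.58, and the covariance was 0.319, against 0.0619. The simulated values follow from the probe error alone. They leave out spread of the day 0 culture or RNA that all probes of a gene share, so they are no full baseline. Genes are not independent replicates. Of genes past the rule at day 1, 552 that rose and 606 that fell did not pass it in the same direction at day 3. Conversely, 151 of the rises and 60 of the falls at day 3 had not passed it in that direction at day 1. Missing the rule at day 3 is not a return to day 0. All genes that rose at day 1 had a median day 3 change of 0.84, against 1.52 at day 1. Those that fell had -0.63, against -1.26.

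From day 1 to day 3, 330 genes rose and 365 fell, of 9318 measured, with a probe error of 0.31 log2. Many moved back toward day 0. Of the genes that had risen at day 1, 285 fell by day 3, and 178 of those that had fallen rose. Because both comparisons use the day 1 array, its error alone makes some genes move back. CD68 fell by 3.00 log2, RAPGEF3 by 2.55, PTPN6 by 2.45, ARHGAP9 by 2.34, PRG2 by 2.12, INPP5D by 1.45 and SIRPA by 1.17. ADGRF5 rose by 2.19, FAM117B by 2.11, DYNC2LI1 by 2.05 and CISD1 by 2.02. Another 12 genes that had risen at day 1 rose again, among them CCL22 by 3.01 and IL12A by 1.55. Of 43 interferon response genes 7 rose between these days and 0 fell, with a median of 0.39 above all 10000 random lists. B cell genes had a median of -0.44, above 28 random lists, and myeloid genes -0.36, above 177. Without background correction 201 genes rose from day 1 to day 3.

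Control genes and ribosomal protein genes served as a background. Of 15 control genes 1, HPRT1, fell by 1.14 at day 1 and 0 passed the rule at day 3, with medians of 0.03 and 0.04, the first 0.21 under median scaling and 0.22 with the mean of a gene's probes, the second -0.08 in the authors' values. GAPDH changed by -0.10 and -0.07 at day 1 and day 3. ACTB changed by -0.21 and 0.00, though another of its probes changed by 1.85 at day 1. Of 44 ribosomal protein genes 0 passed at day 1 and 1, RPS23, fell by 1.28 at day 3, with medians of -0.16 and -0.05. Markers of other cell types stayed mostly below background. Of the probed members, 2 of 28 T and NK cell genes, 5 of 21 erythroid and megakaryocyte genes and 3 of 23 fibroblast and endothelial genes were measured at day 1, and 3, 5 and 3 at day 3. None rose at either day, and HBD was at least 2.92-fold lower at day 1. Their medians were -0.26, 0.03 and 0.40 at day 1 and -0.10, 0.19 and 0.23 at day 3. That of T and NK cell genes at day 3 was 0.02 under median scaling, that of erythroid genes at day 1 -0.050 at a detection p-value under 0.05, and the 1 fibroblast and endothelial gene above background on all arrays changed by -0.19 and -0.23 at day 1 and day 3.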

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

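The tests on the PU.1 probe and on the interferon genes were chosen after the results had been seen. Those on the excess of changes at day 1 were chosen before.

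Probes with no gene name in the table used also changed. Of them, 101 were higher and 89 lower at day 1 by the same size rule, and 52 were higher and 30 lower at day 3. They enter none of the gene counts. RIMKLA was the 1 gene that passed the rule in opposite directions, with a change of -1.10 at day 1 and 1.14 at day 3. That difference was not tested, since each day has 1 array, and RIMKLA was picked after its values were seen. Its changes were -0.79 and 0.97 without background correction and -0.95 and 0.95 in the authors' values, short of 2-fold in each.

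The SPI1 probe was not above background on any array, although the cells were built to switch PU.1 on. Whether the induced PU.1 transcript lies outside the part the probe reads would need a second probe, and the table named 0 other SPI1 probes, so this cannot be told apart from a transcript below the reach of the probe. Nothing here separates a response to PU.1 from other differences between the cultures. A rise of PU.1 itself remains open and untested by these values.

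More genes changed at day 1 than at day 3, 742 against 196 falls and 856 against 455 rises. Error of single probes on the day 1 array would not carry over to other probes of the same genes. Of 606 genes that fell at day 1 only, 34 had a second probe, with a median change of -1.06 (95% bootstrap interval -1.31 to -0.85). Of 552 that rose at day 1 only, 21 had one, with a median of 0.91 (0.46 to 1.11). In the same direction went 33 of the 34 and 18 of the 21, and 20 and 8 were past 2-fold. Both medians argue against single-probe error as the sole source for genes of this kind. Most second probes of the rises were short of the rule, however. For the falls the normalization is argued against too, since those at day 3 were at most 30.3% of those at day 1 under median scaling and in the authors' values. The rises at day 1 were 1.83 times those at day 3 under median scaling and 2.04 times in the authors' values. For the rises no such test was set in advance. At day 3 the same second probes had medians of -0.45 for the falls and 0.46 for the rises, so part of the change remained there. A passing or weakening response of the cells may underlie the excess at day 1. So may a difference of the day 1 culture or RNA that all probes of a gene would share. With 1 array per day nothing here separates them.

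Of 43 interferon response genes 30 rose at day 1 and 33 at day 3. An intensity trend or the normalization would place random lists of like expression as high, but the median at day 3 lay at least 1.81 log2 above the upper end of the middle 95% of such lists, in the own normalization and in the authors' values. In the own normalization that outcome was already known from the random lists above. The authors' values rescale the same intensities, and the list's median of 1.80 there left little room for another outcome. The comparison is therefore no independent test of these explanations. Tetracycline removal, handling or time in culture may raise these genes without PU.1. The series as used here holds 0 arrays of cells without the inducible gene, so these cannot be told apart from an effect of PU.1, which stays a hypothesis.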

How the results depend on the processing

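Each alternative named here was chosen before the data were examined. Leaving out a replicate was not run, and no paired analysis was possible because each day has 1 array. With 22.3% to 23.2% of the probes above background, signal over background limits what can be seen of lowly expressed genes. Of the list medians recomputed, 401 stayed within 1 bootstrap SD of their value and 63 moved further. Of 58 list medians 13 took another sign in at least 1 alternative, all of 0.40 or less in size. Of the changes of named genes, 1711 stayed within the probe error and 255 moved, and 0 called ones changed sign. Detection on all 3 arrays, which removes genes known by a bound, ended 28 of 89 calls of named genes at day 1 and 26 of 96 at day 3. These counts cover only genes taken by the rule for named genes, and the text names other list members too. The authors' values ended 5 and 16, no background correction 10 and 10, an offset of 50 10 and 10, median scaling 0 and 1, and the others 0. By construction a 1.5-fold rule passes more genes, 1687 higher and 1937 lower at day 1, 1088 and 1169 at day 3, 1168 and 1206 from day 1 to day 3, and 745 and 802 at both days. A 3-fold rule passes fewer, in the same order 354 and 127, 177 and 11, 43 and 89, and 118 and 7. Without background correction 98 genes were lower at day 3, 201 rose from day 1 to day 3 and 69 were lower at both days, and with an offset of 50 these were 97, 200 and 68. Both draw the changes of dim probes toward 0. Without background correction the day 1 medians were 1.40 for B cell, 1.41 for interferon and -0.18 for T and NK cell genes, and the day 3 medians 0.46 for MHC class II, -0.28 for DNA replication and 0.61 for glycolysis and hypoxia genes. With an offset of 50 they were 1.40, 1.40 and -0.18, and 0.46, -0.28 and 0.59. In the authors' values the day 1 medians were 1.44 for B cell, 0.70 for MHC class II, -0.52 for DNA replication, -0.22 for mitosis, 0.62 for NF-kB, -0.75 for ribosome biogenesis, -0.22 for ribosomal protein, -0.22 for unfolded protein and -0.21 for T and NK cell genes. Their day 3 medians were 0.38 for MHC class II, -0.25 for G1 cyclin, -0.43 for DNA replication, -0.45 for mitosis, 0.77 for NF-kB, 0.26 for JAK-STAT, 1.80 for interferon, -0.76 for ribosome biogenesis, -0.15 for ribosomal protein, -0.0007 for unfolded protein, -0.45 for heat shock, 0.62 for cholesterol, 0.60 for glycolysis and hypoxia, -0.095 for lysosome and -0.076 for control genes. Except for T and NK cell genes, these lie on the side of that table's shift of the median. That shift, over genes above background on both arrays, was -0.08 at day 1 and -0.10 at day 3. At a detection p-value under 0.05, which admits dimmer genes, the medians at day 1 and day 3 were 0.74 and 0.45 for myeloid and 0.63 and 0.60 for B cell genes, and -0.079 at day 1 for T and NK cell genes. With no filter they were 0.045 and 0.049 for myeloid and 0.11 and 0.075 for B cell genes. With no filter the day 1 medians were also 0.042 for PU.1 partners, 0.12 for AP-1, 1.35 for interferon, 0.30 for glycolysis and hypoxia, 0.0003 for T and NK cell and -0.0028 for fibroblast genes, and the day 3 medians 0.75 for NF-kB, 0.23 for Reed-Sternberg cell and 0.35 for AP-1 genes. On all 3 arrays the myeloid medians were 0.59 and 0.43 and that of fibroblast genes -0.19 at day 1. The mean of a gene's probes gave -0.69 for ribosome biogenesis at day 3 and 0.22 for control genes at day 1. Median scaling gave -0.084 and -0.0077 for ribosomal protein genes and, at day 1, -0.12 for T and NK cell and 0.21 for control genes. For the mean of probes and median scaling the cause was not tested.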

Other observations

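The mitochondrial ribosomal protein genes were chosen, and set against random lists, after the changes at day 3 had been seen.

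Of 28 glycolysis and hypoxia genes 5 rose at day 1, SLC2A3, ENO2, KDM3A, PDK1 and PFKFB4. The median change was 0.52 log2, and 0.30 with no detection filter. The calls of PFKFB4 and PDK1 ended in the authors' values, and those of PFKFB4, PDK1 and KDM3A without background correction. At day 3, 10 of 30 rose (7 in the authors' values) and 0 fell, with a median of 0.76 above all 10000 random lists. PFKFB4, which sets the flux of glycolysis, rose 9.19-fold at day 3, the mitophagy receptor genes BNIP3L and BNIP3 by 2.48 and 2.25 log2 and the glucose transporter gene SLC2A3 by 1.88. Of 19 cholesterol synthesis genes 1, SREBF2, rose at day 1, by 1.35, with a median of 0.09 that was -0.07 in the authors' values. At day 3, 4 rose and 0 fell, STARD4 by 1.53, SQLE by 1.35, FDPS by 1.11 and IDI1 by 1.06, with a median of 0.82 above all 10000 random lists. The calls of FDPS and IDI1 ended in the authors' values, at 0.92 and 0.85. From day 1 to day 3 the cholesterol median was 0.62 and the glycolysis median 0.38.

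Of 31 unfolded protein and amino acid stress genes EDEM1, WARS1 and PPP1R15A rose and HSPA5 fell by 1.02 at day 1, with a median of -0.06. Of 32 measured at day 3, 6 rose and 0 fell, DNAJB9 by 1.61, DDIT4 by 1.56, EDEM1 by 1.24 and WARS1 by 1.13 among them, with a median of 0.14 and, in the authors' values, -0.0007. There 3 rose at day 3 and the call of WARS1 ended, at 0.93, and that of HSPA5 at day 1 ended without background correction and under median scaling. Of 23 heat shock and redox genes TXNRD1 rose by 1.10 at day 1 and DNAJB1 fell by 1.21 at day 3, with medians of -0.27 and -0.31, and the call of TXNRD1 ended in the authors' values. Of 30 lysosome and phagocytosis genes 6 rose at day 1 and CTSC fell by 1.01 (0.98 without background correction), with a median of 0.45 above 9990 random lists. At day 3 CD68, CTSZ (1.17) and GRN (1.07) rose, of 31 measured, with a median of 0.06 that was -0.09 in the authors' values. The calls of CTSZ and GRN ended in the authors' values and without background correction.

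MRPS34 was among the 10 largest falls at day 3, and its family was then looked at as a whole. Of 76 measured genes for mitochondrial ribosomal proteins 24 fell at day 1 and 6 at day 3, and 0 rose. The median change was -0.76 at day 1 and -0.43 at day 3, with 74 of 76 below 0 at day 3. It stayed negative in the other settings tried, at -0.43 without background correction, -0.47 under median scaling and -0.61 in the authors' values at day 3. The medians at day 1 and day 3 lay below those of all 10000 random lists of like expression. Because the family was picked for a member that fell, this tests no explanation.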
